A study of Mus musculus with 7 samples.

How the data were processed

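Chromatin accessibility was measured by ATAC-seq in 7 mouse libraries, 1 per group, each of which came as a list of peaks. Per the labels the E13 cells came from trypsin digests of whole organs and were sorted for a reporter of Shh-expressing epithelium. At E16, forestomach epithelium was freed with dispase, by peeling and with collagenase, and hindstomach, small intestine and colon epithelium with EDTA. The protocol text ends before the knockout library is described. The submitters' processing notes name cutadapt, Bowtie2, MACS2 and GRCm38/mm10; versions, thresholds and any pooling of libraries are not given in the sources used here. The deposited files hold 3 columns, chromosome, start and end of each peak, so their unit is other than a signal: they hold no height, score, p, q or read count, and no normalization applies. Whether positions count from 0 or 1 is not stated, so they are printed as deposited, and depth per library is unknown.

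Peaks on the 19 autosomes and X were kept, which left between 81179 and 135743 peaks per library. Overlapping peaks of the 7 lists (at least 1 bp) were merged into 326695 regions, and a region counted for a library where that library had a peak in it. Chance overlap was measured by shifting the lists along the chromosomes 10 times; over pairs of lists its lowest mean was 1.04% of peaks and its highest value in any shift 2.26%. Each region was assigned to the nearest protein-coding gene body within 100 kb of the GRCm38.p6 RefSeq annotation, which placed 81.0% of regions at 20480 genes. The planned distance to transcription start sites could not be had, since the gene table used gives no strand; a gene end is within 1 kb of either end of a protein-coding gene. Shares have 95% Wilson intervals, which cover counting error only, and libraries were compared by region counts and the Jaccard index of regions, with no test across groups.

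The comparisons, the gene lists, the rule for named genes and the alternatives by overlap, chromosomes, gene assignment and gene-end window were fixed before the data were examined. The 18 lists hold intestinal transcription factors, enterocyte, stomach transcription factor, glandular stomach, squamous epithelium, colon, posterior Hox, proximal small intestine, secretory and endocrine, Wnt and progenitor, Hedgehog pathway, pan-epithelial and housekeeping genes, and markers of mesenchyme, blood and immune cells, endothelium, neural crest and neurons, and liver, lung and pancreas. Of their 250 genes 249 were found in the annotation, and Prac1 was not. For each gene the log2 ratio of regions in the library named first only to regions in the other only was taken with a pseudocount of 0.5. The mean over a list was placed as a percentile among 10000 random lists of the same size, matched in 10 bins of region number per gene, and the difference is the list mean minus the mean of the random lists. Percentiles below 2.5 or above 97.5 are called outside the limits; they are not p values, since genes are not replicates. Named genes are, per comparison, the 8 with the largest excess in each direction (predicted genes and non-coding RNAs left out), the 3 members per list with the largest excess of at least 2 regions, and always Sox2 and Cdx2; the text prints a part of them.

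The list method was tested on simulated data made from hindstomach and intestine, with lists of 20 genes. Without a difference, 9 of 200 lists lay above the upper limit and 5 below the lower one. The planted difference multiplied the odds that an unshared region was hindstomach-only, at a fixed number of unshared regions per gene. With 1.5-fold odds 7 of 20 lists (35.0%) were found, with 2-fold 12 (60.0%) and with 4-fold 20 of 20. A list inside the limits can thus still hold a difference of 1.5-fold or 2-fold in these odds.

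Since the files hold no peak strength, alternatives by strength were replaced, after the data were seen, by the widest peaks of each list at the length of the shortest (81179), the wider part of each list split at its median, and random thinning to that length. The sets of regions shared by all stomach or all intestinal wild-type libraries, and leaving out single libraries from them, were added after the data were seen too. The 20 fixed motifs were not scanned, because no genome sequence was used here. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.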

Results

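The data are ATAC-seq peak lists, positions of open chromatin, from the mouse embryonic gut. There were 7 libraries, 1 per group: stomach and intestine at embryonic day 13 (E13), forestomach, hindstomach, small intestine and colon at day 16 (E16), and E16 stomach with a Sox2 knockout (KO). The wild-type libraries were made from epithelium, whereas the isolation of the KO library is not given in the sources used here. SOX2 is a transcription factor of the foregut, the forestomach becomes squamous epithelium, and the hindstomach becomes glandular epithelium. With 1 library per group there is no spread between replicates, so no difference between groups was tested; intervals are 95% Wilson intervals and cover counting error only. The files give no read depth or peak height, so depth is unknown. The number and width of peaks are given instead, though neither is shown to follow depth. Peaks on chromosomes 1 to 19 and X numbered 96877 in E13 stomach, 81179 in E13 intestine, 87443 in forestomach, 113117 in hindstomach, 97568 in E16 intestine, 135743 in colon and 107067 in KO stomach. They covered 11.9 Mb in E13 intestine at the lowest and 22.8 Mb in KO stomach at the highest. Median widths ran from 108 bp in E13 intestine to 178 bp in forestomach. The smallest width differed between libraries too, at 62 bp in E13 intestine, with 19.4% of its peaks, and 108 bp in forestomach, with 13.8%. A gene end here is the 1 kb on either side of either end of a protein-coding gene, since the annotation used gives no strand. The share of peaks at gene ends was 22.7% (22.4 to 23.0) in E13 intestine, 19.4% (19.1 to 19.6) in E13 stomach and 19.2% (18.97 to 19.44) in KO stomach. It was 16.6% in forestomach, 15.6% in hindstomach, 14.7% in E16 intestine and 10.2% (9.99 to 10.3) in colon, against a mean of 3.34% when the regions were shifted along the chromosomes.

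Merging the 7 lists gave 326695 regions, and the Jaccard index, the share of all regions of a pair that both libraries hold, set the order of likeness. Forestomach and hindstomach were the most alike pair at 0.453. KO stomach and E13 stomach came next at 0.399, above KO with hindstomach at 0.306 and KO with forestomach at 0.263. E16 intestine and colon shared 0.338, hindstomach and E16 intestine 0.331, and E13 stomach and E13 intestine 0.322. The KO stomach shared 0.297 with E13 intestine, above its value with forestomach, and 0.171 with E16 intestine and 0.120 with colon. Away from gene ends KO shared 0.342 with E13 stomach, 0.258 with hindstomach, 0.232 with E13 intestine and 0.212 with forestomach. At gene ends these values were 0.723, 0.620, 0.660 and 0.573.

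**Figure D1:**
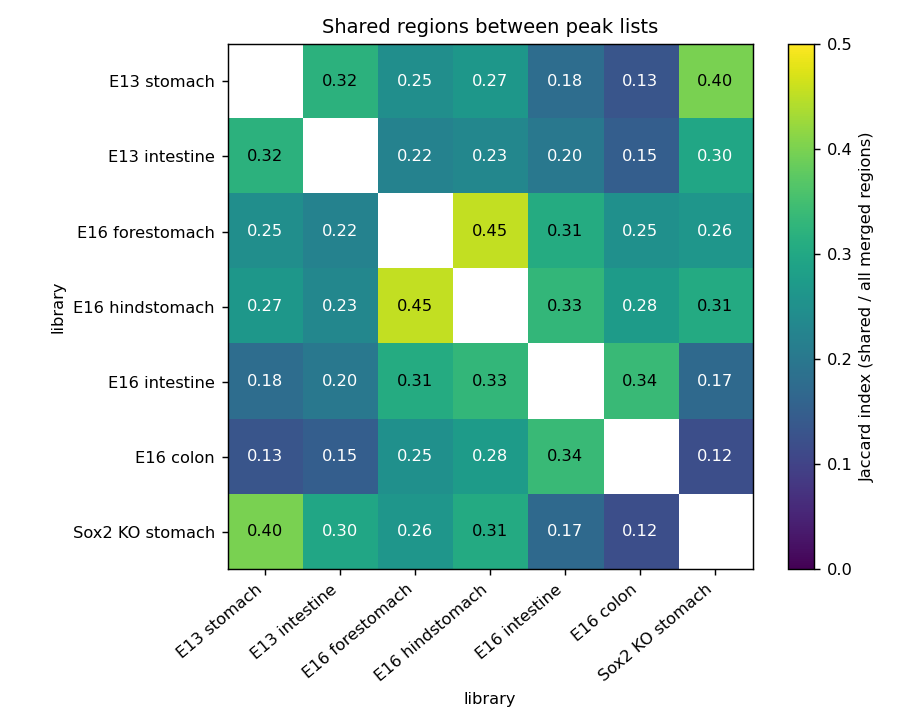
Jaccard index (0 to 1, no unit) of merged regions for each pair of the 7 libraries, which stand along both axes. Forestomach with hindstomach holds the highest value, 0.453, and Sox2 KO stomach with E13 stomach the next, 0.399.

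The E13 comparison of stomach with intestine addressed how the early gut tube is patterned. Regions near Sox2 stood more in stomach, with 8 stomach-only, 2 intestine-only and 1 shared, while Cdx2, an intestinal master regulator, had 1, 1 and 4. Of genes with an unshared region, 58.3% had more stomach-only and 26.8% more intestine-only regions. Among named genes, Pax9, a foregut regulator, had 4 stomach-only and 0 intestine-only regions, Grhl3, an epithelial barrier regulator, 8 and 1, and Irx5, a patterning factor, 8 and 3. Muc5ac, the mucin of stomach surface cells, had 5 stomach-only regions and none in intestine. Hnf4g, an enterocyte transcription factor, had 3 stomach-only and 7 intestine-only regions, and Mep1b, a brush-border protease, 0 and 3. In total 51428 regions were stomach-only (60.1% of the unshared, 59.8 to 60.4), 34142 intestine-only and 40658 shared. The stomach list was longer, and at equal list length the counts lay closer. They were 38465 stomach-only and 36156 intestine-only with the widest peaks, and 43610 and 40763 with lists thinned at random.
Of the 18 gene lists, none lay outside percentiles 2.5 to 97.5 of random lists with as many regions per gene. Squamous epithelium genes stood at percentile 96.6, with 12 members having more stomach-only regions, 2 more intestine-only and 5 equal. Stomach transcription factors stood at 90.2 (7, 1 and 1 members), enterocyte genes at 3.93 (8, 6 and 10) and posterior Hox genes, which pattern the hindgut, at 2.92 (3, 5 and 3). Among genes with the largest excess were Auts2 (42 stomach-only, 16 intestine-only) and Rad51b (38 and 14) for stomach, and Nkain2 (13 and 23) and Kcnip4 (9 and 20) for intestine. Genes named for such an excess had a median length of 557 kb, against 17.1 kb for all protein-coding genes.

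At E16 the comparison of hindstomach with small intestine set glandular stomach beside intestinal epithelium. Glandular stomach genes had more hindstomach-only regions in 14 of 18 members and more intestine-only in 1, with 58 against 13 regions. Among them Anxa10, a gastric annexin, had 14 and 0, Cldn18, the stomach tight-junction claudin, 7 and 2, and Vsig1, a gastric adhesion protein, 6 and 1. Enterocyte genes went the other way in 11 of 24 members, with 5 towards hindstomach and 8 equal. Examples are Apob, which builds chylomicrons, with 2 hindstomach-only and 11 intestine-only regions, and the brush-border peptidase Dpp4, with 1 and 7. Of 10 intestinal transcription factors 6 had more intestine-only regions, among them Isx, a regulator of carotene uptake, with 2 and 8, Maf with 2 and 6 and Hnf4g with 3 and 7. Sox2 had 8 hindstomach-only, 4 intestine-only and 4 shared regions, and Cdx2 0, 0 and 4. The mean log2 ratio of hindstomach-only to intestine-only regions differed from random matched lists by 1.13 for glandular stomach genes (percentile 99.99), by -0.98 for enterocyte genes (0.02, with a median log2 ratio of 0) and by -0.94 for intestinal transcription factors (1.01). Gata4, the transcription factor of glandular stomach and proximal intestine, had 10 and 1, and Ehf, an epithelial transcription factor, 14 and 3. The largest excesses elsewhere were Kalrn (36 and 11) and Cdk19 (23 and 2) for hindstomach and Rbfox1 (22 and 41) for intestine.
Hindstomach-only regions numbered 58228 (57.0% of the unshared, 56.7 to 57.3), intestine-only 43926 and shared 50492. With the widest peaks of each list at equal length the order turned, to 38728 hindstomach-only and 39099 intestine-only. With lists thinned at random to that length it turned too, to 48116 and 48298. The EDTA concentration differed between these tissues.

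Forestomach and hindstomach, the future squamous and glandular stomach, differed in the intestinal transcription factors, the only one of the 18 lists outside its limits here. In hindstomach 9 of the 10 had more regions and 1 had as many, with 27 hindstomach-only against 5 forestomach-only regions. Hnf4g had 0 forestomach-only and 6 hindstomach-only regions, Maf 0 and 4 and Isx 0 and 3. Glandular genes followed in 11 of 18 members, with 5 towards forestomach: Anxa10 had 1 and 8, Cldn18 1 and 6, and Gkn3, a gastrokine of stomach epithelium, 0 and 5. Squamous epithelium genes had more forestomach-only regions in 4 members and more hindstomach-only in 6, and Trp63, the master regulator of squamous epithelium, had 3 and 5. Sox2 had 2 forestomach-only, 6 hindstomach-only and 6 shared regions, and Cdx2 0, 1 and 3. Olfm4, a stem-cell gene, leaned to forestomach with 5 and 0, and so did Btbd11 with 15 and 6.
Hindstomach had more regions of its own genome-wide, so lists are read against matched lists: intestinal transcription factors differed by -1.01 (percentile 0.5), squamous genes stood at 94.1 and glandular genes at 18.6. Forestomach-only regions numbered 24783, hindstomach-only 48202 and shared 60518.
When regions were given to gene bodies extended by 10 kb, the intestinal transcription factors stood at percentile 17.8. With the widest peaks at equal length forestomach-only regions outnumbered hindstomach-only, 27376 to 26336, and with thinned lists they did so too, 38349 to 37814. Tissue went with isolation here, since forestomach was freed with dispase and collagenase and hindstomach with EDTA.

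Small intestine and colon, the absorptive and the distal gut, were compared at E16. Enterocyte genes had 61 intestine-only and 61 colon-only regions where colon had more regions genome-wide: 11 members leaned to intestine, 9 to colon and 4 to neither. Apob had 11 intestine-only and 7 colon-only regions, whereas the peptidase gene Enpep had 5 and 9. Of genes with an unshared region, 24.4% had more intestine-only and 61.7% more colon-only regions. Some other genes leaned to colon: B3galt5, a glycosyltransferase, had 1 and 9, and Muc2, the goblet-cell mucin, 0 and 4. Hoxb13, the most posterior Hoxb gene, had 0 and 2. Slc37a2, of the colon list, went the other way, with 4 regions in intestine and 0 in colon. Posterior Hox genes as a list stood at percentile 63.5, with 3 members towards intestine, 3 towards colon and 5 equal. As a list, colon genes stood at percentile 75.1, with 2 members towards intestine, 4 towards colon and 3 equal. The stem-cell genes Lgr5 (5 and 14) and Smoc2 (5 and 16) had more colon-only regions, and Wnt and progenitor genes as a list stood at 29.0. Sox2 had 2, 12 and 6 regions and Cdx2 0, 0 and 4.
Against matched lists enterocyte genes differed by 0.79 (percentile 99.8, with a median log2 ratio of 0), and blood and immune markers by -0.82 (1.49), with Ptprc, the pan-leukocyte antigen, at 3 and 13 and Runx1 at 7 and 19. Intestine-only regions numbered 36909, colon-only 75667 and shared 57509. With the widest peaks at equal length 36955 colon-only regions remained beside 35846 intestine-only, and blood and immune markers stood at percentile 23.4. Enterocyte genes stood at 95.9 with extended gene bodies and at 94.98 away from gene ends.

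From E13 to E16 intestine, enterocyte genes had more E16-only regions in 16 of 24 members and more E13-only in 2. Apob had 3 E13-only and 12 E16-only regions, Mttp, which loads lipid onto apolipoprotein B, 0 and 9, and the mucin Muc13 0 and 4. Maf had 4 and 11 and Nr1h4, the bile acid receptor, 1 and 7, and intestinal transcription factors as a list stood at percentile 8.75, with 7 of 10 members towards E16. Trp63 ran the other way, with 12 E13-only and 2 E16-only regions. Sox2 had 1, 6 and 2 regions and Cdx2 1, 0 and 4.
Enterocyte genes differed from matched lists by -0.57 (percentile 1.58) and stood at 4.81 away from gene ends. E13-only regions numbered 46523, E16-only 66141 and shared 28277. Stage went with isolation, since E13 cells were sorted and E16 epithelium was released with EDTA.

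In stomach, Anxa10 had 1 E13-only and 15 hindstomach-only regions, Cldn18 0 and 8, and Vsig1 1 and 4. Glandular stomach genes as a list had more hindstomach-only regions in 13 of 18 members and more E13-only in 2. Hedgehog pathway genes, which carry signals between epithelium and mesenchyme, leaned to E13: against hindstomach 6 members did, 2 leaned to hindstomach and 2 were equal, with Hhip at 12 E13-only and 5 hindstomach-only regions and Gli3 at 14 and 9. Against forestomach 8 Hedgehog members leaned to E13 and none to forestomach, with Gli2 at 20 and 7 and Hhip at 13 and 7. Neural crest and neuron markers leaned to E13 against hindstomach in 5 members, to hindstomach in 4, and Ret, the receptor of enteric neuron precursors, had 6 and 0. Trp63 had 9 E13-only and 3 forestomach-only regions, Isx 8 and 1, and Olfm4 3 and 10. Sox2 had 6, 9 and 3 regions against hindstomach and 7, 6 and 2 against forestomach, and Cdx2 2, 1 and 3 and 2, 0 and 3.
Against matched lists glandular genes differed by -0.90 (percentile 0.15), Hedgehog genes by 0.81 (98.6) for hindstomach and 0.75 (97.8) for forestomach, and neural markers by 0.88 (99.0, with a median log2 ratio of 0). Neural markers stood at 81.1 with extended gene bodies, 95.8 away from gene ends and 96.9 with the widest peaks, and the Hedgehog list against forestomach at 87.6 away from gene ends.
Of 92086 E13 stomach regions 46311 (50.3%, 49.97 to 50.61) were in neither E16 stomach library, while 66613 hindstomach and 50245 forestomach regions were absent from E13 stomach. As in intestine, stage went with isolation.

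Among the 4 wild-type E16 tissues, 231878 regions fell into classes by the tissues that held them. Regions of colon alone formed the largest class with 59752 (25.8%), followed by 31085 in all 4 tissues, 27878 in hindstomach alone, 24746 in intestine alone, 18108 in both stomach parts only, 15807 in forestomach alone and 13877 in intestine and colon only. Regions of all 4 tissues lay at gene ends in 28.1% of cases (27.6 to 28.6) and had a median width of 379 bp. Colon-alone regions did so in 2.86% (2.72 to 2.99), with a median width of 103 bp. These are widths of merged regions, which tend to grow with the number of libraries by construction. With the widest peaks of each list at equal length colon-alone regions numbered 28401 and hindstomach-alone 16056; with lists thinned at random, colon-alone regions numbered 38980, those of intestine and colon 8535 and those of all 4 tissues 11150.

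The KO library was compared with both E16 stomach parts, since the part of the stomach it came from, its strain and its isolation are not given in the sources used here. At Sox2 itself (chromosome 3, 34649995 to 34652461, GRCm38) all 7 libraries had a peak within the region at 34649301 to 34650097, beside one end of the gene. The peaks of KO (34649534 to 34650058), E13 stomach (34649361 to 34650097) and hindstomach (34649825 to 34649999) reached into the gene, and those of the other 4 libraries ended before it. Further inside the gene, forestomach had a peak at 34650802 to 34651021 and hindstomach at 34651018 to 34651107, and no other library had one. E13 stomach lacked these inner peaks as KO did, so their lack does not show which part of Sox2 was deleted. Peaks measure open chromatin and not expression. At Cdx2 (chromosome 5, 147300900 to 147307249) the region at 147306791 to 147307428, which spans one gene end, had a peak in KO, hindstomach, both intestine libraries and colon, and none in E13 stomach or forestomach. The KO peaks there (147306791 to 147306937 and 147307110 to 147307232) lay inside the gene, while each of the other 4 libraries had a peak across its end. A region inside Cdx2 at 147306390 to 147306563 had peaks in KO and E13 stomach only. Positions are printed as deposited.

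**Figure D2:**
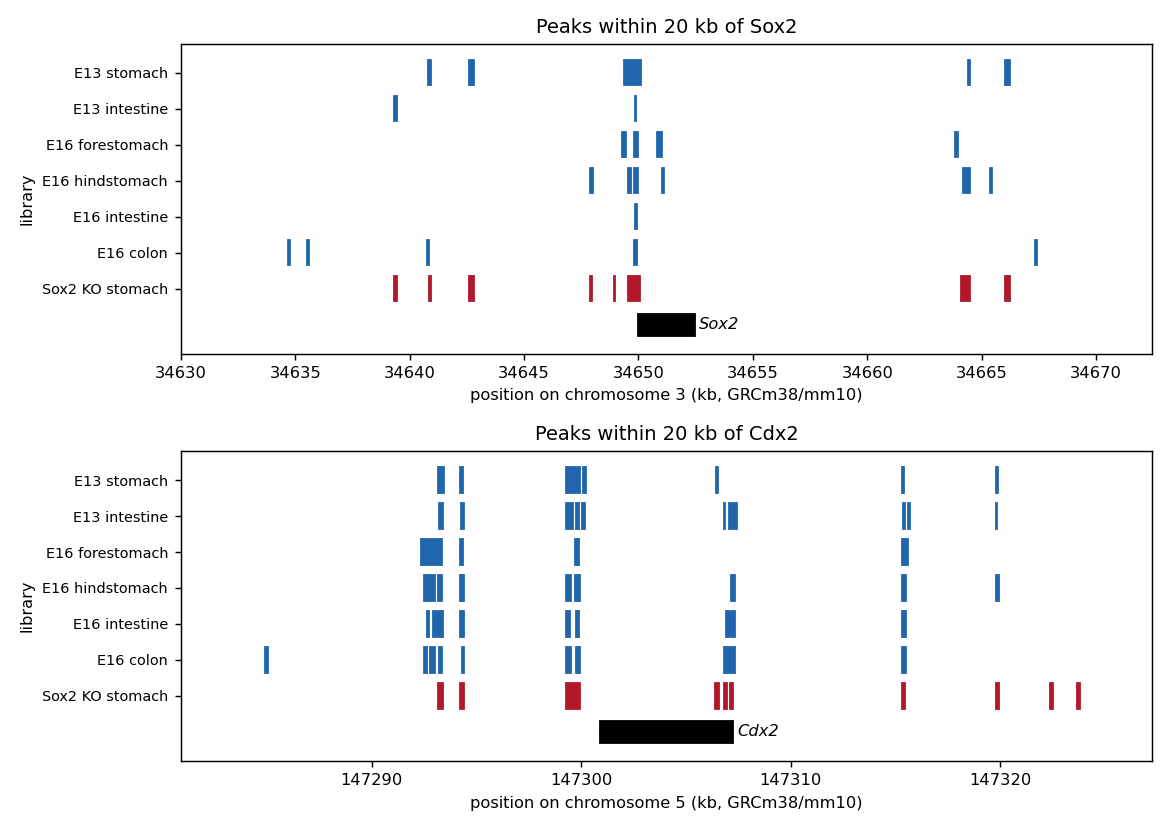
Peaks of each of the 7 libraries as bars (one line per library, KO in red) along the Sox2 and Cdx2 loci, with position in kb on the horizontal axis and the gene as a black bar with 20 kb on either side, all to scale. All 7 libraries have a peak between 34649301 and 34650097, and forestomach and hindstomach alone have one further inside Sox2.

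Regions of both stomach parts and neither intestinal tissue were found in KO in 59.2% of cases (58.5 to 59.9), against 40.8% in E13 stomach and 20.3% in E13 intestine. Hindstomach-alone regions were found in KO in 33.7% and forestomach-alone regions in 17.1% (16.48 to 17.66). Intestine-alone regions were found in 8.12%, those of intestine and colon in 5.04% (4.69 to 5.41) and colon-alone regions in 2.42%. In E13 stomach the last 3 shares were 6.91%, 6.85% and 3.44%. Of 60518 regions present in both stomach parts, 24787 (41.0%, 40.6 to 41.4) had no peak in KO: 6.97% of those at gene ends and 49.6% of those away from them. Of 104039 KO regions 50471 (48.5%) were in neither stomach part. Of these gained regions 32.8% (32.4 to 33.2) were in E13 stomach, 19.5% (19.2 to 19.9) in E13 intestine and 60.7% in neither E13 library. In E16 intestine or colon 8.23% (7.99 to 8.47) were found. The same share in intestine or colon for E13 stomach regions absent from both stomach parts was 10.2% (9.91 to 10.5).

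**Figure D3:**
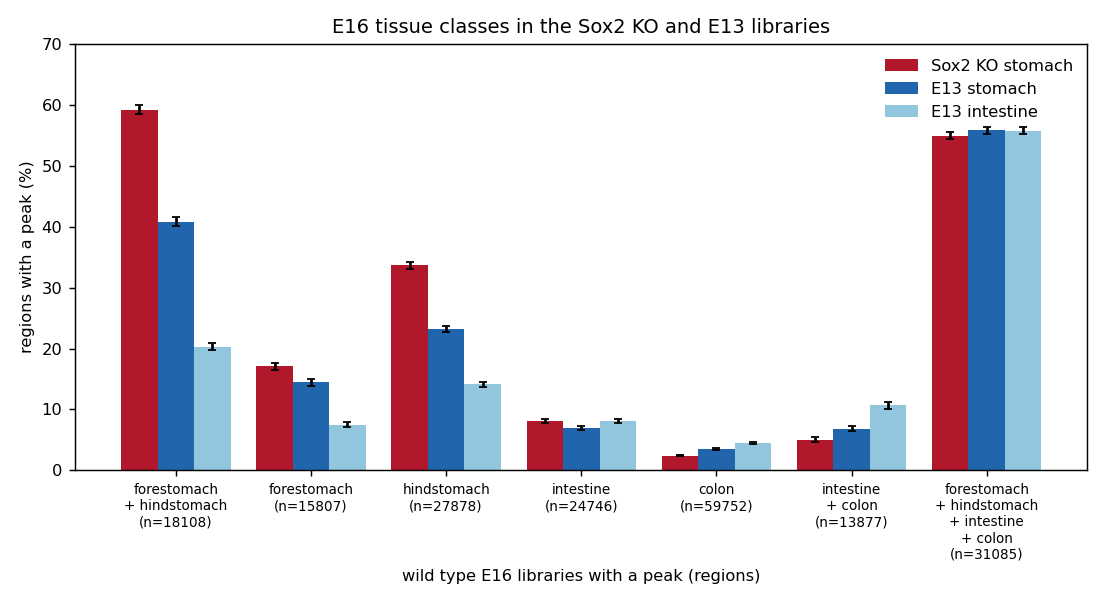
Percent of regions of each E16 tissue class (one group of bars per class) with a peak in Sox2 KO stomach, E13 stomach and E13 intestine, with 95% Wilson intervals as error bars. Regions of both stomach parts reach 59.2% in KO and regions of intestine and colon 5.04%.

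Of all genes with an unshared region, 42.0% had more KO-only and 43.9% more hindstomach-only regions. Against forestomach these shares were 59.4% and 27.8%. Peaks inside gene bodies made up 58.9% in KO, 52.7% in hindstomach and 53.0% in forestomach. The KO stomach had more regions than hindstomach and forestomach around Hedgehog pathway genes. Of these, 9 of 10 members had more KO-only regions and none had more hindstomach-only, and 10 of 10 had more against forestomach. Gli3 had 19 KO-only and 7 hindstomach-only regions and Hhip 17 and 5, and against forestomach Gli2 had 25 and 4. Posterior Hox genes leaned to KO in 7 of 11 members against hindstomach and 9 against forestomach. Hoxa10 had 3 and 0, Hoxa13 3 and 1 and, against forestomach, Hoxb9 5 and 2. The list rests on few regions, 15 KO-only and 6 hindstomach-only, and 21 KO-only and 6 forestomach-only. Hox genes lie side by side in clusters, whereas random lists drew each gene by itself. The members are thus not independent, and the percentiles of this list may be too extreme. Secretory and endocrine genes did so in 10 and 11 of 14 members, among them Nkx2-2 (7 and 2) and Rfx6 (7 and 2), both regulators of endocrine cells, and, against forestomach, Atoh1 (6 and 0), the regulator of secretory cells. Wnt and progenitor genes leaned to KO in 14 of 16 members against hindstomach, with Smoc2 at 18 and 5 and the Wnt target Axin2 at 9 and 4; against forestomach 13 did, with the list inside the limits at percentile 79.2.
Mesenchyme markers leaned the same way in 13 of 18 members against hindstomach, with Meox1 at 6 and 1, whereas Zeb1 had 5 and 10; against forestomach 13 did too, with the list inside the limits at percentile 95.1. Gastric genes were mixed: Anxa10 had 2 KO-only, 13 hindstomach-only and 4 shared regions and Vsig1 0, 4 and 2, while the glandular list stood at percentile 69.2 with 9 of 18 members towards KO and 5 towards hindstomach. Intestinal genes were mixed too: Apob had 14 and 5, Isx 8 and 3, Hnf4a 7 and 3 and Hnf4g 1 and 6. Intestinal transcription factors stood at 48.0 and enterocyte genes at 52.4. Sox2 had 9 KO-only, 8 hindstomach-only and 4 shared regions, and 11, 6 and 2 against forestomach. Cdx2 had 1, 0 and 4, and 2, 0 and 3.
Against matched lists the difference for KO and hindstomach was 1.22 for Hedgehog genes (percentile 99.95), 1.03 for posterior Hox genes (99.4), 0.92 for secretory and endocrine genes (99.0), 0.80 for mesenchyme markers (99.3) and 0.67 for Wnt and progenitor genes (98.6). For KO and forestomach it was 1.15 for secretory and endocrine genes (99.9), 1.09 for posterior Hox genes (99.7) and 1.03 for Hedgehog genes (99.6). Wnt and progenitor genes stood at 97.1 away from gene ends and 88.9 with the widest peaks, and mesenchyme markers at 97.0 with extended gene bodies, 97.1 away from gene ends and 92.5 with the widest peaks.
KO-only regions numbered 54132 against hindstomach and 64647 against forestomach, and the reverse 58813 and 45909.

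Over the 9 comparisons, 19 of 162 list percentiles lay outside 2.5 to 97.5. Nominal limits give 8.1 by chance and the simulation without a difference, with 14 of 200 lists outside, gives 11.3; the comparisons share libraries, so percentiles are not independent. Of these 19 list results, 11 stayed outside the limits under each of the 3 alternatives run for lists. The 14 housekeeping genes lay between percentiles 8.79 and 96.5 in all 9 comparisons, pan-epithelial genes between 6.29 and 96.6, endothelial markers between 7.43 and 89.1, proximal small intestine genes between 7.09 and 96.3, and markers of liver, lung and pancreas between 7.91 and 94.2. Squamous epithelium genes lay between 15.0 and 96.6, colon genes between 22.5 and 75.1 and stomach transcription factors between 5.98 and 91.5.

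**Figure D4:**
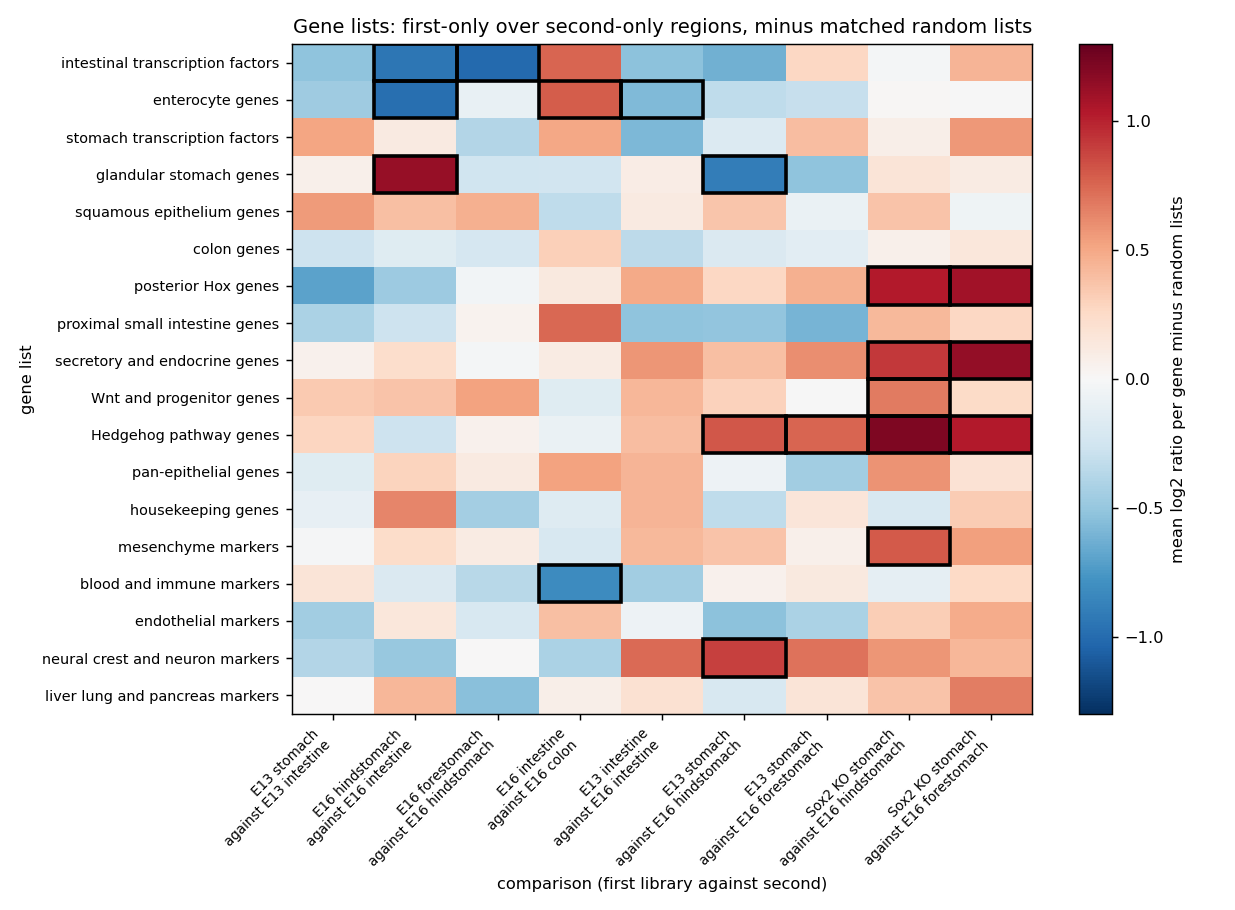
Mean log2 ratio per gene of regions of the library named first only to those of the other library only, minus that of matched random lists (colour), for 18 gene lists (vertical axis) and 9 comparisons (horizontal axis), with the 19 values outside percentiles 2.5 to 97.5 framed in black. Glandular stomach genes stand at 1.13 for hindstomach against intestine and Hedgehog genes at 1.22 for KO against hindstomach.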

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

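These counts come from sequences that the comparisons left out, except in the alternative with all sequences, and no test was chosen for them before or after they were seen; each is named because it exceeds the 3 counts that a count of 0 allows. Peaks on chromosome Y numbered 178 in E13 stomach, 187 in E13 intestine, 565 in forestomach, 639 in hindstomach, 719 in E16 intestine, 1111 in colon and 69 in KO stomach. Peaks on the mitochondrial sequence numbered 4 in hindstomach, 5 in E16 intestine and 5 in colon. The sex of the embryos is not given in the sources used here, and no explanation was tested.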

How the results depend on the processing

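The alternatives by peak width, by thinning and by leaving out libraries, and the stomach and intestine sets, were chosen after the results were seen; the others were fixed before. With the widest peaks the order of hindstomach-only and intestine-only counts turned (38728 and 39099), and so did that of forestomach-only and hindstomach-only (27376 and 26336). Thinning turned both orders too, to 48116 and 48298 and to 38349 and 37814. A result counts as kept here when a count stays within 1.5 times, a share within its interval and a list difference within 1 SD of its random lists, which does not mean that a list stays outside its limits. With all sequences 35 of 35 results were kept. The overlap rule of 50% kept 31 results and moved 4, thinning kept 25 and moved 10, the widest peaks kept 39 and moved 22, extended gene bodies kept 11 and moved 8, and regions away from gene ends kept 16 and moved 3. The wider part of each list moved all 35 results, shares among them, and the gene end window of 2.5 kb moved 7 of 7. All 19 lists outside the limits kept their direction under the 3 list alternatives, and 15, 13 and 15 of them stayed outside with gene bodies plus 10 kb, away from gene ends and with the widest peaks. Another 18, 1 and 6 lists came to lie outside. Leaving out a replicate was not possible with 1 library per group, and no paired analysis was possible because no samples are paired. Alternatives by peak strength, the strongest peaks at equal length and the stronger part of each list, were not run, as the files hold no strength, and neither were the motif alternatives, as no genome sequence was used here. Where no cause is given, the cause was not tested.

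With the wider part of each list fewer peaks entered, so counts were lower by construction, while for the shares the cause was not tested. E13 stomach-only and intestine-only regions numbered 22850 and 14123, hindstomach-only and intestine-only 28641 and 21182, forestomach-only and hindstomach-only 10188 and 22064, and intestine-only and colon-only 17052 and 36368. Between stages, 21071 E13 and 30575 E16 intestine regions were absent from the other, 20610 E13 stomach regions were absent from both E16 stomach parts, and 30864 hindstomach and 22564 forestomach regions were absent from E13 stomach. Regions of 1 tissue alone numbered 6870 in forestomach, 12802 in hindstomach, 11203 in intestine and 29912 in colon; 10574 lay in both stomach parts, 7852 in intestine and colon and 16475 in all 4. For KO, 12197 regions of both stomach parts were absent (37.3%) and 22931 were gained, 37.0% of them in E13 stomach and 8.98% in intestine or colon. KO-only and hindstomach-only regions numbered 25006 and 27284, and KO-only and forestomach-only 29908 and 20310. Of regions of both stomach parts only 53.2% were in KO, and of intestine and colon only 4.48%. The stomach set held 2394 regions with 81.8% in KO, and the intestine set 537 with 13.04%.

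With the widest peaks at equal length, which shortens the longer lists by construction, hindstomach-only regions numbered 38728 against intestine and 26336 against forestomach, and colon-only 36955 against intestine. Hindstomach regions absent from E13 stomach numbered 43576, hindstomach-alone 16056, colon-alone 28401 and those of intestine and colon 9150. Of KO-gained regions 39.3% were in E13 stomach; KO held 56.7% of regions of both stomach parts only, 4.601% of those of intestine and colon, 82.8% of the stomach set and 12.0% of the intestine set. The Jaccard index was 0.435 for E13 stomach and KO, 0.327 for hindstomach and KO, 0.283 for forestomach and KO, 0.491 for both stomach parts, 0.341 for the E13 pair, 0.336 for hindstomach and intestine and 0.370 for intestine and colon. Differences from matched lists were -0.27 for blood and immune markers (intestine against colon), 1.51 for secretory and endocrine genes and 0.79 for Hedgehog genes (both KO against hindstomach).

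With lists thinned at random, which removes shared peaks by construction, 38349 regions were forestomach-only against hindstomach, 38980 in colon alone, 8535 in intestine and colon only and 11150 in all 4 tissues. KO lacked 53.8% of regions of both stomach parts, and 29.9% of gained regions were in E13 stomach and 8.71% in intestine or colon. It held 45.8% of regions of both stomach parts only, 6.73% of those of intestine and colon and 65.6% of the stomach set. With an overlap of at least 50% of the shorter peak, 41.7% of regions of both stomach parts were absent from KO, 31.9% of gained regions were in E13 stomach and 7.93% in intestine or colon, and KO held 57.7% of regions of both stomach parts only.

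Without the forestomach library the stomach set held 7818 regions with 80.2% in KO, without the colon library the intestine set held 2136 with 21.02%, and without the E13 libraries the sets held 18108 and 13877 with 59.2% and 5.04%; fewer libraries define a wider set by construction. A gene end window of 2.5 kb raised the share of peaks at gene ends by construction, to 24.3% in E13 stomach, 27.8% in E13 intestine, 21.8% in forestomach, 21.05% in hindstomach, 19.4% in E16 intestine, 14.2% in colon and 25.2% in KO.

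With gene bodies plus 10 kb the difference from matched lists was -1.36 for intestinal transcription factors in hindstomach against intestine and -0.40 in forestomach against hindstomach, 0.50 for enterocyte genes in intestine against colon and 0.36 for neural markers in E13 stomach against hindstomach. In KO against hindstomach it was 1.49 for posterior Hox, 1.78 for secretory and endocrine and 1.16 for Wnt and progenitor genes, and in KO against forestomach 1.52 for posterior Hox genes. Away from gene ends it was -0.70 for enterocyte genes in hindstomach against intestine, 0.43 in intestine against colon and -0.59 for glandular genes in E13 stomach against hindstomach. Depth is unknown, so a region without a peak in a library was not detected there and is not shown to be closed.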

Other observations

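The stomach and intestine sets and the tests of explanations in this part were chosen after the results were seen, whereas the tissue classes, the Jaccard index and the gene lists were planned. Regions held by all 3 wild-type stomach libraries and by none of the 3 intestinal ones (the stomach set) numbered 4213, and the reverse (the intestine set) 939. Muc5ac, the mucin of stomach surface cells, had 3 stomach-set regions, 1 of them across a gene end (chromosome 7, 141788743 to 141789067), and Gata4, a regulator of stomach and foregut endoderm, had 3, all inside the gene. Sox2 had 1, a region of 709 bp at 34747395 to 34748104 on chromosome 3, 94934 bp from the gene. These 7 regions, picked after their values were seen, all had a peak in KO stomach. Of the stomach set 84.7% (83.5 to 85.7) were in KO, and 646 were absent. Zfp423 had the most stomach-set regions together with Lpp, Abcc4 and Rad51b, 6 each.

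The intestine set gave 1 region to Hnf4a, an enterocyte regulator (chromosome 2, 163580114 to 163580570), and 1 to Hoxb9 (chromosome 11, 96251372 to 96251589), neither with a peak in KO. Isx, an intestinal transcription factor, had 2 (chromosome 8, from 74872410 and from 74921052) and Vil1, the brush-border villin, 1 (chromosome 1, 74409135 to 74409434), all with a peak in KO. Mgam, a brush-border maltase, had 3, none in KO. Of the intestine set 16.3% (14.1 to 18.8) were in KO. Taking each stomach library beside the other 3, of regions of E16 intestine and colon absent from those 3 KO held 2.51%, E13 stomach 4.36%, forestomach 19.7% and hindstomach 35.8%. Of regions in the other 3, KO lacked 9.11%, E13 stomach 20.2%, forestomach 23.4% and hindstomach 6.91%. Without the E13 libraries the sets held 18108 and 13877 regions, with 59.2% and 5.04% in KO. Without the forestomach library the stomach set held 7818 regions, and without the colon library the intestine set 2136.

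One hypothesis is that the KO stomach kept much of its stomach-type chromatin and took on little of the intestinal type. The E16 tissue classes part less cleanly. KO held 15.7% of regions of hindstomach, intestine and colon only and 7.78% of those of forestomach, intestine and colon only. It held 51.5% of those of hindstomach and intestine only and 58.0% of those of both stomach parts and colon only. A low share in KO thus also occurred where a wild-type stomach part had a peak, and does not by itself mark the intestinal type. Lower detection in KO as the whole cause is argued against: weighted to the widths of the intestine set, 68.0% (63.7 to 72.1) of the 500 regions that both E16 stomach parts and E13 intestine alone held were in KO, although at the same widths KO held 24.8% (22.6 to 27.2) of the 1752 regions of every wild-type library but E13 stomach, nearer the 16.3% of the intestine set, so lower detection may account for a part. Narrower regions in the intestine set are argued against as well: weighted to its widths, 79.1% (77.2 to 80.8) of the stomach set were in KO. Of 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05, 3, the real one included, gave at least as many regions as the real one (5152, highest other 7605), and the highest parts the EDTA-isolated hindstomach, intestine and colon from the rest. Both the stomach and the intestine set need peaks in a sorted E13 library and in EDTA-isolated E16 tissue. The stomach set also needs a peak in forestomach, freed with dispase and collagenase, and the intestine set needs none there. The EDTA concentration differed too, and the isolation of KO is not given. Isolation is therefore not fully parted from organ in these sets.

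The KO library shared more regions with E13 stomach (Jaccard 0.399) than with hindstomach (0.306) or E13 intestine (0.297). Whether the KO stomach was completely arrested at the E13 state stays open. Of 10220 regions of both E16 stomach parts absent from intestine, colon and both E13 libraries, 36.5% (35.6 to 37.5) or 3734 were in KO. The share was 1.43% (1.23 to 1.65) for 11988 such intestinal regions, which a stomach library may lack with or without arrest. Gaps in E13 stomach at the rate seen where E13 intestine had a peak (13.6%) would give 702, fewer than the 3734. That rate comes from regions already detected in an E13 library, whereas the 10220 regions were in neither. Gaps may be more frequent among the latter, so the test cannot decide. A library batch or isolation shared by the E13 and KO libraries is a candidate explanation that stays open. Of 35 choices of 4 libraries the wild-type E16 ones, although 4 tissues, ranked 1 in regions found in those 4 only (11048, next 3567). Regions that open between E13 and E16 and that a delayed KO lacks would give the same rank. The rank therefore cannot part batch or isolation from stage. The wild-type E16 libraries did not share 1 isolation either, since forestomach was freed with dispase and collagenase. Whether the KO library held mesenchyme cells stays open. Against hindstomach, mesenchyme markers stood at percentile 99.3 and pan-epithelial genes at 96.6, inside the limits. The first exceeded the second by 0.22 on the log2 scale with a combined SD of 0.46, too little to part them. Meox1 had 6 KO-only and 1 hindstomach-only regions but Zeb1 5 and 10. A partial delay of the KO stomach, which the design allows, was not tested apart from these.

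Colon-alone regions (59752) outnumbered those of any other single E16 tissue, and did so with the widest peaks at equal length (28401). Whether weak or background calls in the colon library account for them stays open: 2.86% (2.72 to 2.99) lay at gene ends, under the highest value of 3.81% for shifted regions, but the share was also 2.93% for regions of intestine and colon only and 2.25% for those that just the 4 wild-type E16 libraries held. Regions near colon genes did not decide it: these genes had 17 intestine-only and 31 colon-only regions, but their mean log2 ratio lay 0.31 (SD 0.45, percentile 75.1) above that of matched lists, which lean to colon more. A difference of the colon itself stays open too.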
